A study of Drosophila melanogaster with 24 samples.

How the data were processed

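RNA from S2 cells, a male-type Drosophila melanogaster cell line, was measured after 2 days of RNA interference (RNAi) with double-stranded RNA against msl1, against msl2, or against GST as the control, per the labels' protocols. Each condition has 4 replicates in 2 assays, which makes 24 libraries in 6 groups. In TT-seq, RNA made during 5 min with 500 µM 4-thiouridine was taken from cells grown at 25 °C and enriched, per the labels' protocols. Total RNA-seq measured the RNA present in the cells. Libraries came from a stranded total RNA kit with removal of ribosomal RNA, per the labels' protocols. Values are called TT-seq RNA and total RNA here.

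The deposited values are a signal: read counts per gene that the authors divided by library size factors, in 4 tables of 17737 genes and 8 libraries, 1 table per assay and RNAi target. The tools named in the submitters' processing notes are STAR 2.7.4a, cutadapt 2.8, SAMtools 1.20, featureCounts and DESeq2, with the genome build dm6. The strand setting and other options of the counting are not given in the sources used here. Values of genes that overlap others are therefore uncertain, as are those of families with close copies. Besides overlaps given beside a value, this holds for CG15312, CG12470, CG16903, Ucp4A, ras, Zw, Pgd, mRpL16, mRpS25, usp, Trf2, Spt6, Sxl, Nup153, UQCR-14, COX6B, Cyp4d2, RpL7A, RpS28b, msl-3, roX1, CG15353, dpr3, alpha-Man-IIb, CR43972, CG14273, CG33307, olf413, CG1910, Myo28B1, Sep2, DptB, AttC, PGRP-SD, Cp1, EcR, ftz-f1, piwi, osk, Dcr-2, egr, Ets21C, Jra, Hsp27, Ald, Pxn, Su(var)3-7 and dup. The deposited gene annotation is on dm6, per its file header, and gave the coordinates. A deposited annotation of transcription units was not used here. All 32 columns were matched to a library by name, and 17599 gene identifiers were matched in a table of gene names.

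Because the normalised counts are multiples of what 1 read is worth, the reads themselves could be recovered: 100% of values came out whole at a tolerance of 0.001 reads. The control libraries stand in both tables of their assay, and their recovered reads were identical there for all 17737 genes. Recovered reads in genes numbered 6.9 M to 20.3 M per TT-seq library and 12.5 M to 35.2 M per total RNA library. Values within a table are relative to that table's scaling, so a change in the amount of all RNA per cell would not be seen. Comparisons between tables used the recovered reads or the difference of fold changes.

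The main test of each RNAi condition against its control was limma 3.58.1 (R 4.3.3) with trend and robust moderation on log2(normalised count + 1), for genes with a mean of at least 10 over the 8 libraries. Benjamini-Hochberg adjusted p-values were called at 0.05. Fold changes are on this log2(value + 1) scale, which understates changes of low genes. The 2 RNAi conditions were compared with each other by edgeR 4.0.16 (quasi-likelihood test, TMM) on recovered reads of 12 libraries, and the TT-seq change was compared with the total RNA change by an interaction term in limma. The X against autosome shift of a comparison was taken from log2 values centred on each gene's mean over the libraries: the median over X-linked genes minus the median over genes of 2L, 2R, 3L and 3R in each library, compared between groups by an exact 2-sided permutation test. Its 70 assignments allow a smallest p of 0.0286. Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data, with adjustment over the sets tested in each table (27 in each TT-seq table and 26 in each total RNA table). Camera ranks a list against all other genes tested, X-linked ones included. Where the X falls, a list of mostly autosomal genes can rank higher for its chromosomes alone. The arms 2R, 3L and 3R themselves ranked higher in each comparison (camera adjusted p under 0.05). Lists were not tested with this chromosome difference removed.

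The gene lists, the main test of each comparison and the rule for named genes were fixed before the data were examined. The tests chosen later are named as such where they are reported. The rule names, in each comparison, the targeted gene and the members of the MSL complex with the roX RNAs, the X-linked readout genes, up to 3 members with the smallest p of each other list, and 6 genes in each of 3 classes: X-linked genes with the largest fall, autosomal genes with the largest fall, and genes with the largest rise. These last classes took genes with adjusted p under 0.05, a mean of at least 100 and no overlap between the values of the groups, and skipped features without a name. The lists are the MSL complex with roX RNAs, X-linked readouts, MSL interactors, the NSL complex, RNA polymerase II with its factors, RNAi machinery, immune genes of the Imd and Toll pathways, apoptosis and JNK, Xrp1 response, heat shock, S phase, mitosis, ribosomal proteins, mitochondrial ribosomal proteins, glycolysis, autophagy and lysosome, ecdysone response, and markers of hemocytes, lamellocytes and crystal cells, germline, neurons and muscle. The names NELF-A, NELF-E, Spt4, Peb and CtsD were not matched, and 369 of the 374 listed names were.

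Whether the replicate numbers pair the samples was checked from deviations from the group means. In the TT-seq msl2 comparison, same-numbered libraries correlated at 0.66, 0.22, 0.32 and 0.13 across genes, each above 0.1, so the rule used here counts them as paired. Only number 1 stood apart in the data. Differently numbered libraries among numbers 2, 3 and 4 correlated at 0.15 to 0.27, and number 1 with another number at −0.47 to −0.26. The pairing of numbers 2, 3 and 4 therefore rests on the labels. In the other comparisons at least 1 of 4 correlations was below 0.1. Replicates were compared with each other by a chi-square test over genes, and the statistic per degree of freedom lay between 2.39 and 127 over 36 pairs, so none was counted as a library deposited in duplicate. Nothing in the sources used here says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

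The methods were tested on simulated data with changes of known size, made from the means and library sizes of the real genes. A single draw was made per setting, with 50 genes changed at each fold. At a fold of 0.5, limma recovered 84% of changed genes in the TT-seq msl1 setting (9140 genes), 96% for TT-seq msl2 (9040 genes), 96% for total RNA msl1 (8479 genes) and 100% for total RNA msl2 (8643 genes). At a fold of 0.75 the shares were 0%, 22%, 48% and 76%. Unchanged genes made up 12%, 7.5%, 4.9% and 4.7% of the calls in these settings, so in both simulated TT-seq settings the share of false calls was above the threshold of 0.05. In the data many X-linked genes changed together, so these shares of recovered and false calls need not hold for the real comparisons. With the msl1 label limma called 18.5% of X-linked genes lower in TT-seq RNA, where the X median was −0.40. For the difference between TT-seq and total RNA, limma recovered 58% of genes changed at a fold of 0.5 and 6% at 0.75 in the msl1 setting (8362 genes), with 10% of calls unchanged genes, and 90% and 28% in the msl2 setting (8451 genes), with 3.8%. Between the labels, edgeR recovered 76% and 10% in TT-seq RNA (9102 genes) and 88% and 70% in total RNA (8596 genes), with 3.5% and 3.4% of calls unchanged genes. Alternatives tried were pseudocounts of 0.5 and 10, no filter or a filter of 50, scaling on autosomal genes, the replicate number as a block, leaving out each replicate, edgeR and DESeq2 1.42.0 on recovered reads, and a trimmed mean. Chosen after seeing the data were fits without libraries that stood apart, array weights, and a set of protein-coding genes with a mean of at least 100. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.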

Results

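Newly made RNA (TT-seq) and total RNA were sequenced from S2 cells treated with RNAi against msl1, msl2 or GST, with 4 libraries in each of the 6 groups. The MSL complex binds the single X chromosome of male flies and raises its transcription, a process called dosage compensation. The series title names transcription initiation and the establishment and maintenance of dosage compensation in male flies. Reads in genes numbered 6.9 M to 20.3 M per TT-seq library and 12.5 M to 35.2 M per total RNA library. The annotation held 2671 genes on the X, 3496 on 2L, 3621 on 2R, 3457 on 3L, 4191 on 3R and 111 on chromosome 4.

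The targeted genes were higher, not lower, in the libraries that carry their RNAi label. msl-1 (FBgn0005617, 2L, 18683720 to 18688800 on the minus strand of dm6), the scaffold of the MSL complex, stood at 173 ± 3.9 CPM, counts scaled to the reads in genes (SD, n = 4), in control TT-seq RNA and at 616 ± 322 in libraries labelled msl1 RNAi, which lay between 311 and 1055. In total RNA, msl-1 stood at 151 ± 2.9 in control libraries and at 990.2 ± 340.0 in those labelled msl1 RNAi, between 491 and 1223. msl-2 (FBgn0005616, 2L, 3462218 to 3466112, minus strand), the subunit made in males, stood at 51.9 ± 3.5 in control TT-seq RNA and at 445 ± 121 in libraries labelled msl2 RNAi, between 344 and 614. In total RNA, msl-2 stood at 75.1 ± 4.7 and 1216 ± 87.3, with libraries labelled msl2 RNAi between 1151 and 1342. mir-4971 lies inside msl-2 on the same strand, so reads of the 2 genes cannot be separated. roX2 (FBgn0019660, X, 11579065 to 11580432, plus strand), a noncoding RNA of the MSL complex, fell from 565 ± 21.2 in control total RNA to 106 ± 2.8 in libraries labelled msl1 RNAi and 152 ± 5.8 in those labelled msl2 RNAi. Since the targeted genes go against the labels, conditions are named throughout as the libraries labelled msl1 RNAi or msl2 RNAi, and every direction below rests on these labels.

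**Figure D1:**
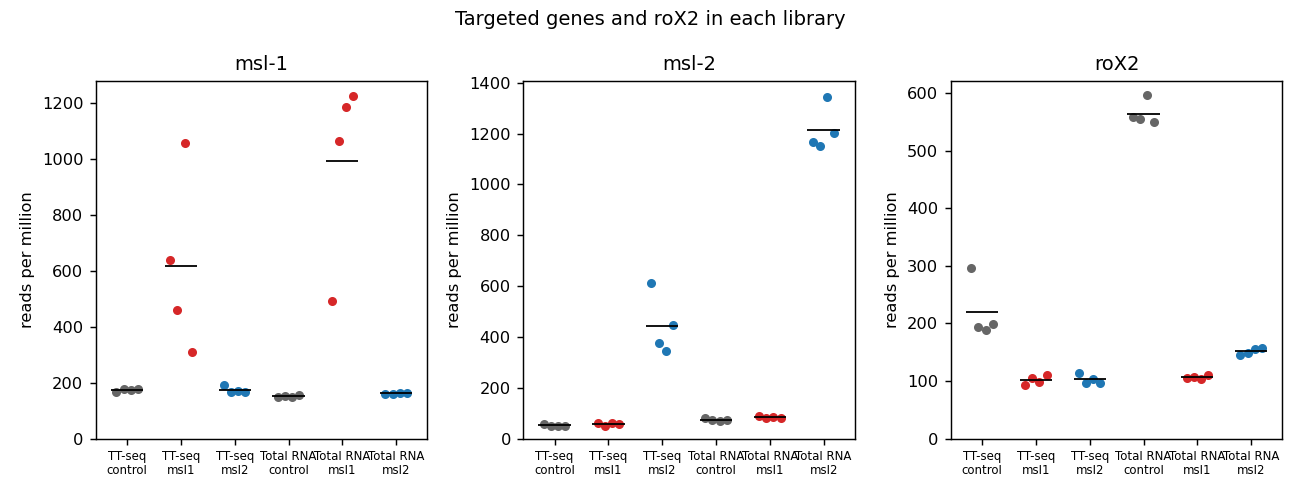
CPM (reads of a gene scaled to the library's reads in genes) for msl-1, msl-2 and roX2 in each TT-seq and total RNA library, with a line at the mean of each group of 4. In total RNA, msl-2 lies between 1151 and 1342 in libraries labelled msl2 RNAi against a control mean of 75.1, while roX2 falls from a mean of 565 to 106 and 152.

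The first comparison asks how newly made RNA differed between the libraries labelled msl1 RNAi and control. X-linked genes were lower as a group: the X against autosome shift was −0.48 on the log2 scale, which is 28.5% lower, from 0.24 ± 0.008 in control libraries to −0.24 ± 0.02 in those labelled msl1 RNAi (SD, n = 4 each; exact permutation p = 0.0286, the smallest possible). roX2 fell from 2884 ± 523 to 1346 ± 92.7 normalised counts, a log2 change of −1.09 ± 0.13 (SE, limma adjusted p = 0.0097). The potassium channel gene eag changed by −1.04 ± 0.13 and arm, the fly β-catenin (FBgn0000117, X, 1891401 to 1900646, minus strand), by −0.57 ± 0.12, although arm overlaps mRpL16 on the other strand and is uncertain for that reason. The odorant-binding protein gene Obp99a rose by 1.67 ± 0.33 and the Golgi mannosidase gene alpha-Man-IIb by 1.05 ± 0.14.

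Of 9205 genes tested by limma, 366 changed in TT-seq RNA with the msl1 label, 58 higher and 308 lower, and edgeR called 442. On the X, 3 were higher and 287 lower of 1553 tested, and on the autosomes 55 were higher and 21 lower of 7563 (47 and 44 with scaling on autosomal genes). Genes are ranked here within the limits of the rule for named genes, a mean of at least 100 and no overlap between the values of the groups. The X-linked genes with the largest falls besides roX2 were then CG15312 (−1.58 ± 0.19), CG42541 (−1.08 ± 0.15), HP1D3csd (−1.07 ± 0.17), eag and the microtubule-associated protein gene futsch (−1.02 ± 0.13, overlapping Gr2a). Among autosomal genes CG33543 (−1.67 ± 0.29, overlapping CR43464), CG15353 (−1.32 ± 0.27), CR45245 (−1.31 ± 0.28), the peroxiredoxin gene Prx2540-2 (−1.15 ± 0.27), dpr3 (−1.12 ± 0.17) and the ubiquitin ligase gene LUBEL (−1.11 ± 0.20) fell most within these limits. The largest rises within them were msl-1 (1.69 ± 0.32, limma adjusted p = 0.0249), Obp99a, CG11658 (1.38 ± 0.16), the semaphorin genes Sema5c (1.26 ± 0.21) and Sema2a (1.04 ± 0.25), and alpha-Man-IIb. Prx2540-2 has close copies and is uncertain. The X-linked genes that rose, ade5 (0.58 ± 0.13), Shmt (0.44 ± 0.10) and CR43864 (0.91 ± 0.18), were chosen after their values were seen. The count is fragile: limma called 0 genes without control library 2, 3 or 4 (1226, 1272 and 1250 at unadjusted p under 0.05), 127 without msl1 library 1 and 183 without msl1 library 2. Scaling on autosomal genes gave 592 and DESeq2 722.

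In the same comparison, 1 of 7 measured genes of the MSL complex with the roX RNAs rose and 1 fell, msl-1 and roX2, while the log2 changes of msl-2 (0.15), msl-3 (0.17), the acetyltransferase gene mof (−0.11), the helicase gene mle (−0.07) and roX1 (−0.25) did not pass. Of 10 measured X-linked readout genes, 4 fell, Ucp4A (−0.64 ± 0.11), arm, ras (−0.54 ± 0.12) and dlg1 (−0.50 ± 0.11), and 8 fell when adjusted over the list alone (limma's camera adjusted p = 1.58e-06, and adjusted p = 0.0648 with an estimated correlation). The X as a set was lower with camera adjusted p = 9.34e-75, and adjusted p = 0.000251 with an estimated correlation. Of 13 S phase genes, 2 rose, PCNA (0.86 ± 0.17) and the replicative helicase gene Mcm5 (0.90 ± 0.18), and 7 adjusted over the list alone (camera adjusted p = 0.000149, and adjusted p = 0.478 with an estimated correlation). Of 10 mitosis genes 0 passed in limma, over all genes or adjusted over the list alone, and camera gave adjusted p = 0.001 (adjusted p = 0.613 with an estimated correlation). Of 18 immune genes of the Imd and Toll pathways 1 rose, AttA (0.62 ± 0.14), and 2 adjusted over the list alone (camera adjusted p = 0.733). Of 13 RNA polymerase II genes 2 fell, both X-linked, Trf2 (−0.62) and the largest subunit gene RpII215 (−0.45). None of the 13 apoptosis and JNK genes, 6 NSL complex genes and 10 MSL interactor genes passed over all genes in limma, and 1 MSL interactor was lower adjusted over the list alone. With scaling on autosomal genes 5 readouts fell (adjusted p = 0.0203 with an estimated correlation), 0 immune genes and 2 MSL interactors (lower) passed, and the medians of the immune, NSL and RNA polymerase II lists turned from above to below 0.

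The second comparison asks the same of newly made RNA with the msl2 label. The X against autosome shift was −0.39, which is 23.4% lower, from 0.19 in control libraries to −0.19 ± 0.004 in those labelled msl2 RNAi (n = 4 each; exact permutation p = 0.0286; 0.125 with the replicate number as a block, the smallest its 16 arrangements allow). roX2 changed by −0.99 ± 0.11 (limma adjusted p = 0.00159), the ion channel gene iav by −1.15 ± 0.11 and the integrin gene if by −0.97 ± 0.17. The antifungal peptide gene Drs rose from 99.8 ± 5.42 to 282 ± 26.8 normalised counts (SD, n = 4, limma adjusted p = 0.000156) together with other immune genes. msl-2 itself was higher by 3.14 ± 0.14 (limma adjusted p = 5.43e-06).

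Of 9073 genes tested by limma, 824 changed in TT-seq RNA with the msl2 label, 213 higher and 611 lower. With the replicate number as a block 2608 changed, 1281 higher and 1327 lower, and 822 of the genes were shared with the unblocked 824. On the X 4 were higher and 510 lower of 1543, and on the autosomes 207 were higher and 100 lower of 7443. The balance of autosomal calls depended on the fit, with 1250 higher and 403 lower under the block, and 146 higher and 150 lower with scaling on autosomal genes. X-linked CG12470 (−1.02 ± 0.17), CG34417 (−0.93 ± 0.07) and CG42541 (−0.92 ± 0.12) fell with iav, if and roX2. Autosomal Prx2540-2 (−1.49 ± 0.24), CG33543 (−1.26 ± 0.23), sick (−1.16 ± 0.18, overlapping small nuclear RNA genes), CG13305 (−1.09), CR45245 (−0.93) and CG13992 (−0.90) fell most among genes with a mean of at least 100 and no overlap between the groups. Within the same limits, the largest rises after msl-2 and Drs were 28SrRNA-Psi:CR40741 (1.27 ± 0.34), CR44241 (1.11 ± 0.24) and ND-51L2 (1.04 ± 0.22), both of which overlap Trpm, and the stress peptide gene TotM (1.06 ± 0.23). The X-linked genes that rose were ade5 (0.35), CG5273 (0.55), Muc14A (0.65) and 28SrRNA-Psi:CR40741, of which the first 3 were chosen after their values were seen. Without control library 1 limma called 1279 genes, and 421, 490 and 407 without control library 2, 3 or 4. Without msl2 library 2, 3 or 4 it called 436, 401 and 407.

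Among immune genes 10 of 19 rose and 0 fell with the msl2 label in TT-seq RNA, also 10 adjusted over the list alone, with camera adjusted p = 3.02e-09 (adjusted p = 0.00803 with an estimated correlation). With the block 12 rose, with camera adjusted p = 3.36e-09 and adjusted p = 0.153 with an estimated correlation. Attacin genes AttA (0.98 ± 0.12) and AttB (0.86 ± 0.10), which are close copies of each other and uncertain, and the diptericin genes DptA (1.17 ± 0.30) and DptB (0.64) were among them. Of the 7 MSL complex genes with the roX RNAs, msl-2 rose and the X-linked roX2 and mof (−0.28 ± 0.07) fell. Of 10 X-linked readouts 4 fell, ras (−0.83 ± 0.10), Ucp4A (−0.49 ± 0.10), arm (−0.45 ± 0.07) and the deubiquitinase gene Usp7 (−0.32 ± 0.07), and 6 adjusted over the list alone (camera adjusted p = 0.00015, and adjusted p = 0.0185 with an estimated correlation). With the block 1 readout rose and 8 fell, with adjusted p = 0.153 with an estimated correlation. Of 13 S phase genes 1 rose, PCNA (0.43 ± 0.10), and 1 adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.78 with an estimated correlation), against 9 higher and 1 lower with the block. Of 10 mitosis genes 1 rose, the cyclin gene CycB (0.47 ± 0.07; camera adjusted p = 0.018, and adjusted p = 0.78 with an estimated correlation), against 5 with the block. Of 13 RNA polymerase II genes 4 fell, all X-linked, Spt6 (−0.59), RpII215 (−0.37), NELF-B (−0.42) and Cdk7 (−0.55), and 5 adjusted over the list alone. In the NSL complex wds (−0.39) fell and among MSL interactors the nucleoporin gene Nup153 (−0.26), both X-linked. The median change of all X-linked genes was −0.33. Of the MSL interactors 3 were lower adjusted over the list alone or with scaling on autosomal genes, and 1 was higher and 3 lower with the block. None of 13 apoptosis and JNK genes passed in limma, against 5 higher with the block (camera adjusted p = 0.0367, and adjusted p = 0.708 with an estimated correlation). Without replicate number 1, a fit chosen after seeing the data, 12 immune genes rose (adjusted p = 0.103 with an estimated correlation), and 1 readout rose and 9 fell (adjusted p = 0.0979 with an estimated correlation). In that fit 9 S phase genes rose and 1 fell, 5 mitosis genes rose, 2 NSL genes fell, 1 MSL interactor rose and 3 fell, and 4 apoptosis and JNK genes rose and 1 fell.

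In total RNA, the libraries labelled msl1 RNAi showed an X against autosome shift of −0.45, which is 26.9% lower, from 0.23 in control libraries to −0.22 ± 0.009 (n = 4 each; exact permutation p = 0.0286). roX2 fell from 11998 ± 493 to 2208 ± 64.5 normalised counts, a log2 change of −2.44 ± 0.05 (limma adjusted p = 1.99e-09). All 10 measured X-linked readout genes fell, among them arm (−0.67 ± 0.06) and the pentose phosphate genes Zw (−0.49) and Pgd (−0.48 ± 0.06). Obp99a rose by 1.23 ± 0.10 and the metallopeptidase gene Nep4 by 0.90 ± 0.08, and msl-1 was higher by 2.59 ± 0.28 (limma adjusted p = 0.000505).

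Of 8510 genes tested by limma, 1481 changed in total RNA with the msl1 label, 418 higher and 1063 lower, against 218 higher and 1273 lower with scaling on autosomal genes. On the X 11 were higher and 852 lower of 1474, and on the autosomes 403 were higher and 209 lower of 6960, a balance that turned with scaling on autosomal genes, to 207 higher and 342 lower. Among genes with a mean of at least 100 and no overlap between the groups, the largest falls on the X after roX2 were Tango2 (−1.17 ± 0.18), CG9917 (−1.14 ± 0.08), eag (−0.95 ± 0.07), and the respiratory chain genes UQCR-14 (−0.93 ± 0.26) and COX6B (−0.93 ± 0.17). Within these limits autosomal falls were led by the glutathione transferase gene GstE2 (−0.85 ± 0.09), CR43972 (−0.75), CG14273 (−0.73), CG7778 (−0.71), CG33307 (−0.69) and CG9338 (−0.69). CG17839 (1.39 ± 0.15), Obp99a, olf413 (1.01 ± 0.11), Nep4 and CG32115 (0.90 ± 0.13) rose most after msl-1 within them. CG14798 (1.73), which has a lower mean and was chosen after its values were seen, rose more. Without msl1 library 1 limma called 2711 genes, and 921, 976 and 966 without control library 2, 3 or 4.

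Of 6 measured MSL complex genes with the roX RNAs, msl-1 rose and the X-linked roX2 and mof (−0.20 ± 0.05) fell in total RNA with the msl1 label. The X-linked readouts had camera adjusted p = 2.38e-08 (adjusted p = 0.0226 with an estimated correlation), with 10 lower also adjusted over the list alone, and the log2 changes of the remaining members, all lower, were −0.86 for mRpL16, −0.54 for Ucp4A, −0.46 for dlg1, −0.40 for ras, −0.39 for Usp7, −0.30 for Klp3A and −0.27 for par-6. Of 13 S phase genes 9 rose, such as Mcm5 (0.37), Mcm2 (0.35 ± 0.06) and PCNA (0.34), and the X-linked Mcm6 (−0.39) and Mcm3 (−0.23) fell, with 10 higher and 2 lower adjusted over the list alone and 5 higher and 2 lower with scaling on autosomal genes (camera adjusted p = 0.00349, and adjusted p = 0.255 with an estimated correlation). Of 10 mitosis genes CycB (0.21) rose, and 5 adjusted over the list alone (camera adjusted p = 0.00735, and adjusted p = 0.376 with an estimated correlation). Among 19 immune genes AttC (0.45 ± 0.11) and AttB (0.34) rose and the cecropin gene CecC (−0.50 ± 0.08) fell, 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.977). Their median was −0.15, and scaling on autosomal genes gave 1 higher and 2 lower. Of 12 apoptosis and JNK genes 4 fell, the TNF gene egr (−0.42 ± 0.04), the cytokine gene upd3 (−0.41), the Jun gene Jra (−0.29) and Ets21C (−0.25), also 4 adjusted over the list alone (camera adjusted p = 0.111). X-linked Trf2 (−0.55), Spt6 (−0.53), Cdk7 (−0.51) and RpII215 (−0.38) fell among 13 RNA polymerase II genes. Among 6 NSL genes MBD-R2 (0.16) rose and the X-linked wds (−0.36) fell, 2 higher and 1 lower adjusted over the list alone, and 0 higher and 1 lower with scaling on autosomal genes. Among 10 MSL interactors Su(var)3-7 (0.24) rose and the X-linked Sxl (−0.45) and Nup153 (−0.43) fell, 1 higher and 3 lower adjusted over the list alone or with scaling on autosomal genes. The median change of all X-linked genes was −0.41 in this comparison.

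Total RNA of the libraries labelled msl2 RNAi showed an X against autosome shift of −0.36, which is 22.3% lower, from 0.18 in control libraries to −0.18 ± 0.009 (n = 4 each; exact permutation p = 0.0286). roX2 fell from 14799 ± 605 to 3899 ± 178 normalised counts, a log2 change of −1.92 ± 0.04 (limma adjusted p = 4.92e-18). CG16903 (FBgn0040394, X, 2078343 to 2080405, minus strand) changed by −1.62 ± 0.05 and the proteasome subunit gene Rpn1 (FBgn0028695, 3L, 19915051 to 19918160, plus strand) by −0.77 ± 0.03. Drs rose by 1.61 ± 0.08 and DptB by 1.02 ± 0.10, and msl-2 was higher by 3.98 ± 0.05 (limma adjusted p = 2.12e-14).

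Of 8678 genes tested by limma, 2626 changed in total RNA with the msl2 label, 1158 higher and 1468 lower, against 664 higher and 1794 lower with scaling on autosomal genes. On the X 24 were higher and 986 lower of 1501, and on the autosomes 1127 were higher and 470 lower of 7098, which turned with scaling on autosomal genes, to 643 higher and 730 lower. X-linked CG34417 (−1.06 ± 0.12), the cytochrome P450 gene Cyp4d2 (−0.94 ± 0.17), CG6903 (−0.93 ± 0.06) and Grip (−0.93 ± 0.12) fell with roX2 and CG16903. Autosomal CG1910 (−1.02 ± 0.05), the myosin gene Myo28B1 (−0.97 ± 0.15), CG5033 (−0.86 ± 0.04), the septin gene Sep2 (−0.81 ± 0.04), Gli (−0.78 ± 0.19) and Rpn1 fell most among genes with a mean of at least 100 and no overlap between the groups. Within these limits the largest rises after msl-2 and Drs were CG30048 (1.33 ± 0.34), Obp99a (1.23 ± 0.08), CG17839 (1.03 ± 0.14) and DptB. CG14798 (1.49), which has a lower mean and was chosen after its values were seen, rose more.

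Among immune genes 13 of 19 rose and 0 fell in total RNA with the msl2 label, 14 adjusted over the list alone, with camera adjusted p = 2.18e-07 (adjusted p = 0.0531 with an estimated correlation). With scaling on autosomal genes 12 rose, with adjusted p = 0.0348 with an estimated correlation. DptA (2.31-fold) and the recognition protein gene PGRP-SD (0.42 ± 0.07) were among them. All 10 X-linked readouts fell, from −0.62 for Zw and −0.55 for mRpL16 to −0.12 for Klp3A, with arm at −0.53 ± 0.03 and Pgd at −0.45 ± 0.04 (camera adjusted p = 1.99e-08, and adjusted p = 0.00383 with an estimated correlation), and 10 adjusted over the list alone. Of 7 MSL complex genes with the roX RNAs, msl-2 and msl-3 (0.22 ± 0.06) rose, and the X-linked roX2, mof (−0.16 ± 0.04) and roX1 (−1.39 ± 0.48, from 14.7 to 5.5 normalised counts) fell. Of 10 mitosis genes 7 rose, such as the Cdc25 gene stg (0.35 ± 0.04), CycB (0.29) and polo (0.13), also 7 adjusted over the list alone but 3 with scaling on autosomal genes (camera adjusted p = 0.00172, and adjusted p = 0.446 with an estimated correlation). Of 13 S phase genes 7 rose, such as dup (0.27) and dap (0.27), and 2 fell, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0556). Of 12 apoptosis and JNK genes 5 fell, Ets21C (−0.29), upd3 (−0.29), egr (−0.24), Jra (−0.24) and Diap1 (−0.13), also 5 adjusted over the list alone (camera adjusted p = 0.0355, and adjusted p = 0.4 with an estimated correlation). Of 13 RNA polymerase II genes 5 fell, all X-linked, among them Spt6 (−0.48), Trf2 (−0.47) and RpII215 (−0.30), and 3 rose, among them Taf1 (0.22). Of 6 NSL genes 4 rose and 1 fell (2 and 1 with scaling on autosomal genes), and of 10 MSL interactors 2 rose and 2 fell (1 and 2). Those of these 2 lists that fell are X-linked, and the median change of all X-linked genes was −0.32.

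**Figure D2:**
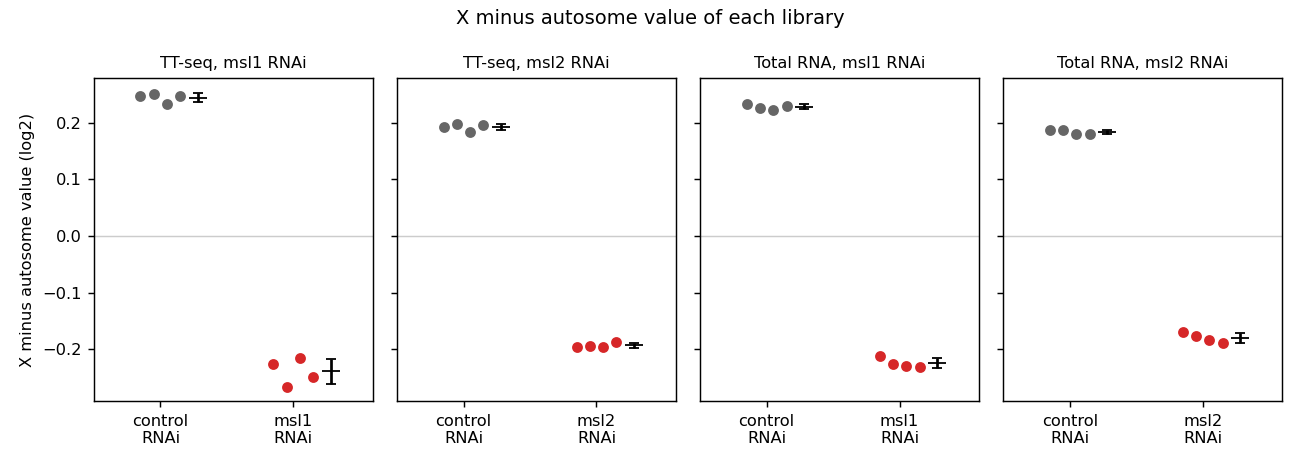
X against autosome value (log2) of each library in the 4 tables, with the mean of each group of 4. The shifts between groups are −0.48, −0.39, −0.45 and −0.36 for TT-seq msl1, TT-seq msl2, total RNA msl1 and total RNA msl2.

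**Figure D3:**
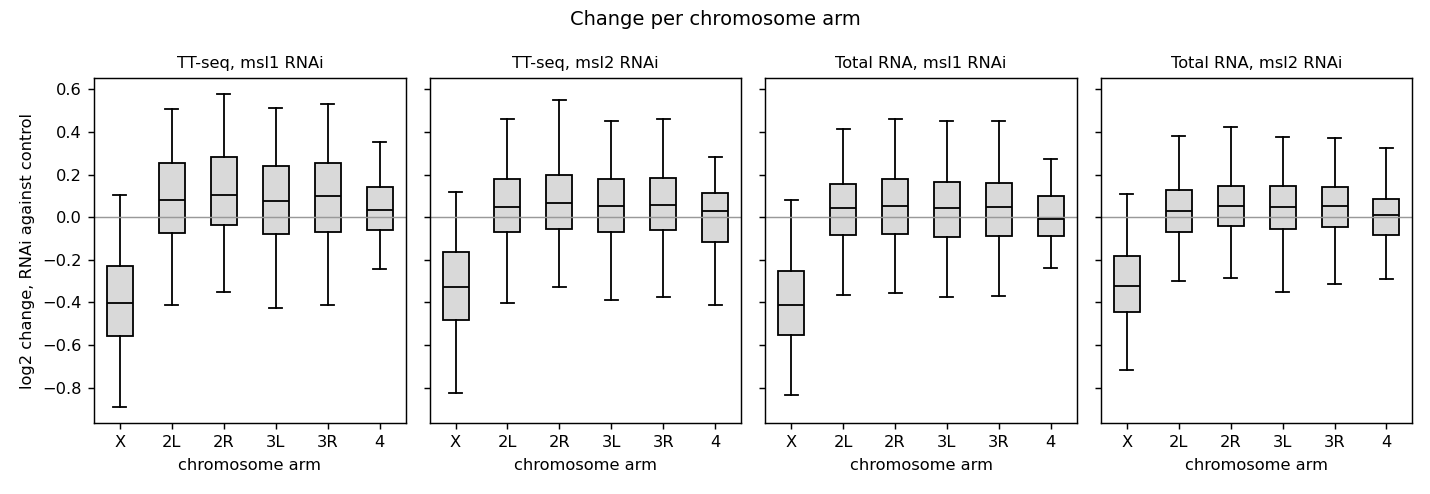
Log2 change per gene by chromosome arm in the 4 comparisons, with boxes at the quartiles and whiskers at percentiles 5 and 95. The median of the X is −0.40, −0.33, −0.41 and −0.32 for TT-seq msl1, TT-seq msl2, total RNA msl1 and total RNA msl2.

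The lower level of X-linked RNA extended along the whole X. In bins of 2 Mb with at least 20 genes, each of the 12 X bins had a median change below that of all 49 autosomal bins, in each of the 4 comparisons. Smaller autosomal bins were left out, and in TT-seq RNA with the msl1 label some of them were low: −1.02 for the first bin of 3R, which holds 1 gene, and −0.29 and −0.24 for the first bins of 2R, with 12 and 7 genes. X bins lay between −0.44 and −0.33 in TT-seq RNA and between −0.46 and −0.32 in total RNA with the msl1 label, against −0.02 to 0.19 and −0.04 to 0.11 on the autosomes. For the msl2 label they lay between −0.37 and −0.23 in TT-seq RNA and between −0.36 and −0.22 in total RNA. Chromosome 4 genes gave 0 calls of 86 in TT-seq RNA with the msl1 label by limma, 2 higher and 1 lower of 85 with the msl2 label, and 4 higher and 2 lower of 75 and 7 higher and 12 lower of 78 in total RNA. Within 3 classes of mean level and 3 classes of gene length, the X against autosome shift lay between −0.51 and −0.35 in every class, each with exact permutation p = 0.0286.

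**Figure D4:**
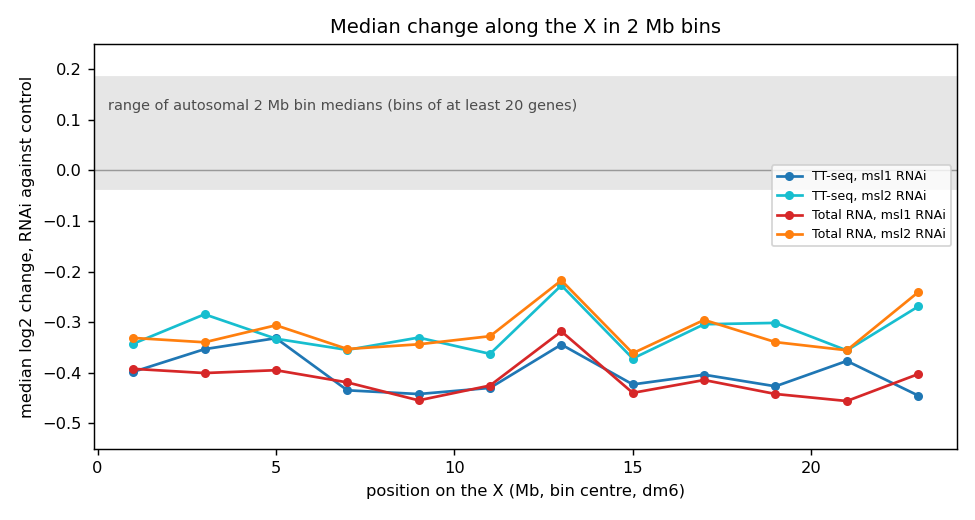
Median log2 change of genes in 2 Mb bins along the X for the 4 comparisons, with a grey band over the range of autosomal bins of at least 20 genes. All 12 X bins lie below the band in each comparison, between −0.46 and −0.22.

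TT-seq RNA and total RNA were then compared for the same RNAi label, which asks whether newly made RNA changed as much as the RNA present. With the msl1 label the X against autosome shift over the genes measured in both was −0.49 in TT-seq RNA and −0.45 in total RNA, a difference of −0.0333 (exact permutation p = 0.0286). With the msl2 label the shifts were −0.38 and −0.36, a difference of −0.0185 (exact permutation p = 0.0571). roX2 changed less in TT-seq RNA than in total RNA with the msl1 label, by 1.36 ± 0.14 (limma adjusted p = 0.000265), and with the msl2 label by 0.93 ± 0.12 (limma adjusted p = 0.00189). roX2 was the single gene of 8400 that passed with the msl1 label by limma (235 at unadjusted p under 0.05, 1 by edgeR), and msl-1 gave −0.90 ± 0.45 (limma adjusted p = 0.996). With either label the roX2 difference no longer passed with the replicate block or without replicate number 2, 3 or 4, where it lay between 1.23 and 1.34 with the msl1 label and between 0.85 and 0.94 with the msl2 label.

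By limma, 20 of 8492 genes differed between TT-seq and total RNA with the msl2 label, against 25 by edgeR, and 765 at unadjusted p under 0.05. The change was less negative or more positive in TT-seq RNA for 15 of them, 5 on the X and 10 on the autosomes. Rpn1 differed by 0.74 ± 0.07 (limma adjusted p = 0.000115), CG16903 by 0.92 ± 0.10 (0.000482), CG1910 by 0.93 ± 0.12, CG5033 by 0.67 and Sep2 by 0.59, along with jumu (0.82 ± 0.11), ClC-a (0.83) and wgn (0.58), which were chosen after their values were seen. The 5 others were msl-2 (−0.85 ± 0.15, limma adjusted p = 0.0221), futsch (−0.54), and, chosen after their values were seen, Tpc2 (−0.94 ± 0.17), CG15784 (−0.48) and THADA (−0.36). The count was not stable: 2 genes passed without replicate number 2, 0 without number 3 (limma, 408 at unadjusted p under 0.05), 1 without number 4 and 2 with the block, while 842 passed without number 1, all 20 among them.

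**Figure D5:**
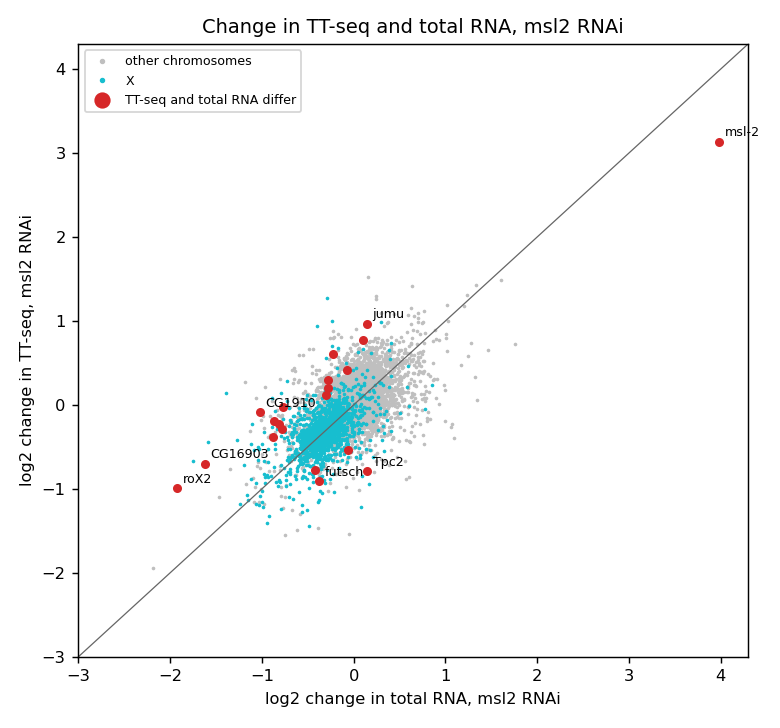
Log2 change in TT-seq RNA against log2 change in total RNA with the msl2 label, for 8492 genes of which 1467 are X-linked. roX2 changes by −0.99 in TT-seq RNA and −1.92 in total RNA.

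The libraries labelled msl1 RNAi and msl2 RNAi were compared with each other. The X was lower with the msl1 label, by −0.11 in TT-seq RNA (7.1% lower; −0.49 ± 0.02 against −0.38 ± 0.007, SD, n = 4) and by −0.09 in total RNA (6.2% lower; −0.46 ± 0.01 against −0.36 ± 0.009), each with exact permutation p = 0.0286. Drs was lower with the msl1 label than with the msl2 label by −1.53 in TT-seq RNA and −1.55 in total RNA, and the immune genes had a median of −0.35 and −0.47 (camera adjusted p = 5.03e-10 and 1.83e-11, and adjusted p = 0.0284 and 0.0552 with an estimated correlation), a list test chosen after seeing the data. CG16903 was higher with the msl1 label by 1.21, CG5033 by 1.07, CG1910 by 0.97 and Rpn1 by 0.83 in total RNA.

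In TT-seq RNA 3 of 9156 genes differed between the 2 labels by edgeR, msl-2 (−3.005, adjusted p = 1.08e-07), Drs (adjusted p = 0.000855) and CG9624 (−0.85, adjusted p = 0.0231), which was chosen after its values were seen. There were 1058 at unadjusted p under 0.05 and DESeq2 called 52. In total RNA 168 of 8653 differed by edgeR, 51 higher and 117 lower with the msl1 label, 7 and 46 of them on the X, and DESeq2 called 374. msl-1 differed by 2.62, msl-2 by −3.86 and roX2 by −0.51 (edgeR adjusted p = 2.3e-05). Without msl1 library 1, edgeR called 633 genes in total RNA, against 104 and 109 without msl1 library 2 or 3, and 86, 76, 79 and 101 without msl2 library 1, 2, 3 or 4. In TT-seq RNA it called 5 without msl1 library 2 and 6 without msl1 library 3.

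The calls of the 2 RNAi labels overlapped. Of 9041 genes tested in both TT-seq tables, 25 were higher in both and 232 lower in both, against 1.33 and 20.8 for independent lists. Of 8489 in total RNA, 285 were higher and 927 lower in both, against 56.5 and 184. In opposite directions stood 0 genes in TT-seq RNA by limma, and 5 in total RNA: CG5033 (0.20 with the msl1 label, −0.86 with the msl2 label), Idgf6 (0.28, −0.20), CG7139 (0.20, −0.12), CR44953 (−0.23, 0.12) and red (−0.17, 0.21), all but CG5033 chosen after their values were seen. Both labels share control libraries, and unchanged groups were simulated against those, with each gene drawn independently. Their lists held at most 0.1 calls on average, so 0 shared calls was fixed in advance and says nothing about the overlap. The simulated correlation of changes across genes was 0.499 in TT-seq and 0.503 in total RNA, against 0.694 and 0.702 observed. The covariance was 0.0741 against 0.0248 simulated in TT-seq RNA, and 0.0602 against 0.0162 in total RNA. With the controls split between the labels, TT-seq RNA gave correlations of 0.304 to 0.565 and could give no shared call, since limma called 0 genes with the msl1 label in each split, and total RNA gave 29 to 39 genes higher and 335 to 391 lower in both, with correlations of 0.450 to 0.535. The common fall of the X is part of these values. Over autosomal genes alone the correlation was 0.598 in TT-seq RNA and 0.566 in total RNA, against 0.497 and 0.504 simulated. With the controls split it was 0.119 to 0.449 and 0.236 to 0.337. Genes are not independent replicates.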

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

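Only the tests of deeper sequencing were written before their result was seen; the other tests that weigh explanations below, and the counts of other splits of the libraries, were chosen only after the result was seen, and some of their criteria were revised with values already known.

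More genes passed the threshold in total RNA than in TT-seq RNA, 1481 against 366 with the msl1 label and 2626 against 824 with the msl2 label. Deeper sequencing of total RNA is argued against, since total reads thinned to TT-seq depth still gave at least 1294 and 2206 genes over 5 draws. A smaller change of the X in TT-seq RNA is argued against with the msl1 label, where the difference was −0.0333 (exact permutation p = 0.0286). That call depends on how libraries of the assays are matched, with a largest exact permutation p of 0.0571 over all matchings. With the msl2 label the X change was not smaller either, at 103 to 107% of that in total RNA over the settings, although the difference did not pass (−0.0185, exact permutation p = 0.0571). A larger spread between TT-seq libraries is a candidate explanation, with a residual SD 1.65 and 1.86 times that of total RNA at matched reads. No biological explanation was tested.

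With the msl2 label, 15 genes had a lower change in total RNA than in TT-seq RNA, with medians of −0.77 and −0.03. A general compression of changes in TT-seq RNA is argued against by size: the X shift in TT-seq RNA was 105% of that in total RNA (103 to 107% over the settings tried), where 3.9% would be needed. That 3.9% comes from libraries that picked the set and is made lower by the choice, but the X shift showed no compression in any setting. Loss of dosage compensation of the X with either label stays open for the 5 genes on the X. For the 10 on the autosomes their position argues against it as a direct cause, and indirect effects stay open. Of the 15 genes, 11 were called lower in total RNA with the msl2 label and 8 with the msl1 label (limma). 6 genes were lower with the msl2 than the msl1 label (edgeR), but that test uses total RNA libraries that picked the set. With the msl1 label total RNA of these 6 changed by 0.20 for CG5033, 0.06 for Rpn1, −0.10 for CG1910, −0.27 for Sep2, −0.42 for CG16903 and −0.46 for Nrd1. CG5033 and Rpn1 thus fell with the msl2 label (−0.86 and −0.77) but not with the msl1 label. The other 9 had a median of −0.29 with the msl1 label. Transcripts matching the msl2 double-stranded RNA may also remain, as its sequence is not given in the sources used here: 8 genes were also lower with the msl1 label, against control libraries that picked the set, and the others had a median of 0.044. The set is not stable, since of all 20 genes that differed between assays 2, 0 and 1 calls were left without replicate number 2, 3 or 4 (limma, 408 at unadjusted p under 0.05 without number 3; edgeR was not run there) and 2 with the block.

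The targeted gene was higher in libraries labelled with its own RNAi. In 16 of 16 such libraries the gene named by the label was above every library of the other groups. This speaks against single libraries mixed up between labels but restates the pattern, so an exchange of whole groups is not excluded by it. With the msl1 and msl2 labels exchanged, the targets would still not be below control. In TT-seq RNA msl-1 was at 173 CPM in control and msl2 libraries, and msl-2 at 51.9 in control and 57.6 in msl1 libraries. A mix-up within 1 label would not be seen. TT-seq msl1 library 4 correlated at 0.69 with total RNA msl1 library 1 and at −0.44 with total RNA msl1 library 4. In that first pair 0.10% and 0.05% of reads were in ribosomal RNA genes, the lowest of their groups. For msl-2, reads from the added double-stranded RNA are a candidate source, since its rise was smaller in TT-seq than in total RNA by −0.85 ± 0.15 (limma adjusted p = 0.0221), a call lost with the block and without replicate number 2, 3 or 4 (−0.81, −0.67 and −0.88). For msl-1 the difference was −0.90 ± 0.45 (limma adjusted p = 0.996), which decides nothing. Higher transcription cannot be told apart from it for either gene, with rises in TT-seq RNA of 1.69 for msl-1 and 3.14 for msl-2, and read positions were not analysed here.

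Other splits of the libraries into groups of the same sizes, 35 in each case, were counted. For TT-seq RNA with the msl1 label chance was not excluded: 2 splits gave as many genes, the real one with 366 and another with 563, which set control library 1 and msl1 libraries 1, 3 and 4 against the rest and points to a structure of the samples. On the difference between total and TT-seq RNA, the deviations of control library 1 and msl1 libraries 1 and 3 had slopes of 0.253, 0.147 and 0.379, against −0.015 for msl1 library 4 and −0.103 to −0.053 for the rest. In total RNA against control (1481 and 2626 genes) and between the labels (3 and 168), 1 split, the real one, gave as many. The highest other split gave 0 genes by the same tools. Chance is not excluded by this, since 1 of 35 is the smallest share possible and the test was chosen after the result was seen. Mixed splits also carry any real change in their spread, which holds their counts down. The 824 genes of TT-seq RNA with the msl2 label and the 20 that differed there between TT-seq and total RNA were also matched by 1 of 35 splits, the real one (highest other 0). For the single gene that differed between TT-seq and total RNA with the msl1 label 1 of 35 splits, the real one, gave as many (highest other 0). That single call is lost with the block and without replicate number 2, 3 or 4, so nothing is read from it. The counts of 824 and 20 come from fits without the replicate block, although the rule counts these TT-seq libraries as paired by replicate number. With the block the counts were 2608 and 2. Only number 1 stood apart in the data. The 8 splits that part every pair are too few for a share under 0.05.

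Single libraries lay far from the other 3 of their group in 4 of 32 tests of library values and 22 of 262 tests of named genes. Chance gives about 1 in 20 for independent tests, which these are not. Control libraries stand in both tables of an assay, so the same value can be flagged in each, and genes share libraries. Genes with a read numbered 12789 in TT-seq msl1 library 3 (others 13583 to 13675) and 10902 in total RNA control library 4 (others 11760 to 11912). The slope of a library's deviation on the difference between total and TT-seq RNA was 0.253 in TT-seq control library 1 (others −0.103 to −0.061) and 0.159 in TT-seq msl2 library 1 (others −0.041 to −0.024). In normalised counts of the TT-seq msl1 table, control library 1 had roX2 at 3659, msl-3 at 358, mle at 1883 and Obp99a at 85.0, and control library 3 had Usp7 at 2422. There, msl1 library 1 had roX2 at 1208 and msl1 library 3 had mle at 1788. In the TT-seq msl2 table, control library 1 had roX2 at 3204, msl-3 at 313 and mle at 1649, and msl2 library 1 had CG33543 at 339, sick at 766 and Pgd at 901. In the total RNA msl1 table, msl1 library 1 had COX6B at 1020, control library 1 had CG32115 at 317 and control library 3 had Klp3A at 2171. In the total RNA msl2 table, control libraries had roX1 at 24.1 (library 4), Myo28B1 at 258 (library 1) and Klp3A at 2676 (library 3), and msl2 library 1 had CG5033 at 985, Sep2 at 2919 and DptB at 3828.

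Differences between assays or labels that passed their own test were as follows. The X against autosome shift differed between assays by −0.0333 with the msl1 label, and between labels by −0.107 in TT-seq and −0.0926 in total RNA. Between assays 1 gene differed with the msl1 label, roX2 (1.36), and 20 with the msl2 label, among them CG1910 (0.93), roX2 (0.93), CG16903 (0.92), Rpn1 (0.74), CG5033 (0.67), Sep2 (0.59), futsch (−0.54) and msl-2 (−0.85). Between labels 3 genes differed in TT-seq RNA, among them msl-2 (−3.005) and Drs (−1.53), and 168 in total RNA. In total RNA, msl-1 (2.62), CG16903 (1.21), CG5033 (1.07), CG1910 (0.97), Rpn1 (0.83), CG6903 (0.58), Sep2 (0.56), Nep4 (0.55) and Sema2a (0.35) were higher with the msl1 label. Lower with it were msl-2 (−3.86), Drs (−1.55), DptB (−0.83), CG7778 (−0.64), TotM (−0.58), roX2 (−0.51), CG14273 (−0.51), CG9338 (−0.45), GstE2 (−0.45), CG9917 (−0.33) and dlg1 (−0.19).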

How the results depend on the processing

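Fits without libraries that stood apart, array weights, protein-coding genes alone and overlaps by other tools were chosen after seeing the data; the other settings were planned. No shift and no change of a named gene that had passed reversed its sign, but with autosomal scaling the balance of autosomal calls turned in 3 comparisons, from 207 higher and 100 lower to 146 and 150 in TT-seq msl2, from 403 and 209 to 207 and 342 in total msl1, and from 1127 and 470 to 643 and 730 in total msl2. Of the main results 155 values stayed the same, 46 moved, 2 became stronger and 13 weaker, and of the single genes 6325 stayed the same, 225 became stronger and 525 weaker. Unless its construction shows it, the cause was not tested. In TT-seq RNA with the msl1 label (366 genes), no filter gave 210, autosomal scaling 592, DESeq2 722, leaving out all libraries number 1 241 and array weights 1331, and leaving out 1 library gave 0 to 510 (limma). With the msl2 label (824) the replicate block gave 2608, leaving out number 1 2700, array weights 2415 and leaving out 1 library 401 to 1279. In total RNA with the msl1 label (1481) array weights gave 2925 and leaving out 1 library 921 to 2711, and with the msl2 label (2626) leaving out 1 library gave 2161 to 2637. Between assays with the msl1 label the block gave 0 genes (limma, 235 at unadjusted p under 0.05) and leaving out a replicate number 0 to 1 (0 without 2, 3 or 4, with 152, 115 and 195 at unadjusted p under 0.05), and with the msl2 label the block gave 2 and leaving out a number 0 to 842. Between labels DESeq2 gave 52 in TT-seq and 374 in total RNA, and leaving out 1 library 2 to 6 and 76 to 633 by edgeR. Genes called with both labels in TT-seq RNA numbered 468 by DESeq2.

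With the replicate block, the X against autosome shifts of −0.4834, −0.3851, −0.4523 and −0.3632, the difference between assays of −0.0333 and the differences between labels of −0.1065 and −0.0926 had exact permutation p = 0.125, the smallest the 16 arrangements allow, so this says nothing about stability. Leaving out 1 library moved the 4 shifts between −0.4954 and −0.4706, −0.3892 and −0.3764, −0.4593 and −0.4483, and −0.3659 and −0.3594. Without msl1 libraries 3 and 4 the TT-seq msl1 shift was −0.4898 (exact permutation p = 0.0667, the smallest its 15 assignments allow). The difference between assays with the msl1 label lay between −0.0383 and −0.0232 without 1 replicate number (exact permutation p = 0.1, the smallest possible), and the largest p over all matchings of libraries was 0.0571. For the msl2 label (−0.0185) it lay between −0.0203 and −0.017, a trimmed mean gave −0.0252 (exact permutation p = 0.0286), and the smallest p over matchings, which leave the value at −0.0185, was 0.0286. Between labels the range was −0.113 to −0.1008 in TT-seq RNA and −0.0998 to −0.0889 in total RNA. Apart from the TT-seq msl2 comparison, replicate numbers did not meet the rule for pairs against control: correlations were 0.49, 0.25, −0.29 and 0.19 in TT-seq msl1, 0.22, −0.04, 0.17 and 0.04 in total msl1, and 0.24, 0.07, 0.07 and 0.01 in total msl2. Whether numbers pair msl1 with msl2 libraries was not checked. Small changes can be missed: at a fold of 0.75 simulated changes were recovered in 0% of genes in the TT-seq msl1 setting and 76% in the total RNA msl2 setting. Only 50 genes were changed at that fold, so these shares need not hold in the data, where X-linked genes fell together. The simulations did not separate depth from spread.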

Other observations

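The lists in this part were fixed before the data were examined, and the fits without replicate number 1 were chosen after seeing the data. In total RNA with the msl2 label 4 of 13 heat shock genes fell, also 4 adjusted over the list alone (camera adjusted p = 0.117): the small heat shock genes Hsp23 (−0.55 ± 0.05, limma adjusted p = 1.06e-06), Hsp26 (−0.32) and Hsp27 (−0.27), and the co-chaperone gene stv (−0.56). With the msl1 label 1 fell, Hsp23 (−0.37), and 0 adjusted over the list alone by limma, and in TT-seq RNA 0 passed with either label by limma, against 3 lower with the block and 4 lower without replicate number 1 for the msl2 label (camera adjusted p = 0.0703 and 0.00155, and adjusted p = 0.89 and 0.522 with an estimated correlation). The germline genes piwi and osk rose in total RNA, piwi by 1.05 ± 0.18 with the msl1 label and 0.93 ± 0.16 with the msl2 label and osk by 0.45 and 0.42, which makes 2 of 4 measured (1 higher and 1 lower for the msl1 label with autosomal scaling), while 0 of 5 passed in TT-seq RNA by limma. Of 11 Xrp1 response genes 3 rose in total RNA with the msl2 label, chinmo (0.22), GstD1 (0.24) and GstD3 (0.21), also 3 adjusted over the list alone (camera adjusted p = 0.0242, and adjusted p = 0.358 with an estimated correlation), and 0 passed by limma in the other comparisons. TT-seq RNA with the msl2 label gave 3 higher with the block and 5 without replicate number 1. No gene of the Xrp1 list lies on the X, and its median in total RNA with the msl2 label was 0.07, against 0.05 over autosomal genes. In that comparison limma called 15.9% of all autosomal genes higher. Of 6 RNAi machinery genes Dcr-2 (0.11) rose in total RNA with the msl2 label, a call lost with autosomal scaling, and 0 passed elsewhere by limma. There, TT-seq RNA with the msl2 label gave 1 higher and 1 lower both with the block and without replicate number 1. Among hemocyte markers the peroxidasin gene Pxn fell in total RNA with the msl1 label (−0.26) and the msl2 label (−0.49 ± 0.06), and Ppn (0.20) rose with the latter. In TT-seq RNA 0 of 8 passed by limma, against 3 higher with the block and 2 without replicate number 1 for the msl2 label (camera adjusted p = 0.12 and 0.0374, and adjusted p = 0.618 and 0.522 with an estimated correlation). Of 2 lamellocyte and crystal cell markers PPO3 fell with both labels (−0.33 and −0.20) and lz with the msl2 label (−0.83 ± 0.27) in total RNA. In TT-seq RNA 0 of 3 passed by limma, against 1 lower with the block and 2 without replicate number 1 for the msl2 label. Of 4 neural markers nSyb (1.00 ± 0.37) rose in total RNA with the msl2 label, 0 adjusted over the list alone and 0 with autosomal scaling, which gave 1 lower in both total RNA comparisons and in TT-seq RNA with the msl1 label, and 0 passed elsewhere by limma. TT-seq RNA gave 1 higher with the block or without replicate number 1 for the msl2 label. Of muscle markers, 2 were measured with the msl1 label and 1 with the msl2 label in TT-seq RNA, and 0 passed.

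Of 84 ribosomal protein genes 0 passed in TT-seq RNA with either label by limma (camera adjusted p = 5.26e-05 and 0.0366, and adjusted p = 0.892 and 0.855 with an estimated correlation). With the block 26 rose and 2 fell in TT-seq RNA with the msl2 label, with camera adjusted p = 0.00022 and adjusted p = 0.89 with an estimated correlation, and 50 rose without replicate number 1. In total RNA 3 rose and 6 fell with the msl1 label, 2 and 4 adjusted over the list alone (camera adjusted p = 0.344), with a median of 0.01 that turned to −0.04 with autosomal scaling. With the msl2 label 3 of 85 rose and 16 fell, 3 and 14 adjusted over the list alone (camera adjusted p = 0.142, and adjusted p = 0.91 with an estimated correlation), and 1 and 24 with autosomal scaling (camera adjusted p = 0.0107, and adjusted p = 0.685 with an estimated correlation), and the X-linked RpL7A (−0.34) and RpS28b (−0.34) were among those that fell. Of 72 mitochondrial ribosomal protein genes 0 passed in TT-seq RNA with the msl1 label by limma (camera adjusted p = 0.0194, and adjusted p = 0.892 with an estimated correlation) and 4 fell with the msl2 label, all X-linked, mRpS25 (−0.74), mRpL3 (−0.57), mRpL38 (−0.49) and mRpS30 (−0.42), against 2 higher and 7 lower with the block, 1 higher and 6 lower without replicate number 1, and 6 lower with autosomal scaling. In total RNA 3 rose and 9 fell with the msl1 label, 3 and 8 adjusted over the list alone, and 7 rose and 9 fell with the msl2 label, 5 and 9 adjusted over the list alone, which became 0 and 10 and 3 and 9 with autosomal scaling. The median of this list turned with autosomal scaling from 0.02 to −0.03 in TT-seq RNA and from 0.03 to −0.01 in total RNA with the msl2 label. Of 7 autophagy and lysosome genes the X-linked Atg8a fell in TT-seq RNA with the msl1 label (−0.50) and the msl2 label (−0.43) and in total RNA with the msl1 label (−0.69), beside CtsB1 (−0.39). In TT-seq RNA with the msl2 label Cp1 (0.42) and Mitf (0.34) rose and Atg13 (−0.24) fell, and in total RNA with that label 3 rose and 2 fell (1 and 2, and 1 and 3, with autosomal scaling). Of 11 ecdysone response genes the receptor partner gene usp fell in TT-seq RNA by −0.52 with the msl1 label and −0.49 with the msl2 label, and Eip93F by −0.83 ± 0.14 and −0.59, while ftz-f1 (0.40) rose with the latter, a call lost with autosomal scaling. With the latter label the block gave 5 higher and 2 lower, as did the fit without replicate number 1. In total RNA EcR (0.18) rose and usp (−0.40) fell with the msl1 label, and 4 of 10 rose and 1 fell with the msl2 label, against 0 higher and 2 lower, and 1 higher and 1 lower, with autosomal scaling. Of 11 glycolysis genes 0 passed in TT-seq RNA with the msl1 label by limma and PyK (0.29) rose with the msl2 label (0 with autosomal scaling, 2 higher and 3 lower with the block or without replicate number 1). In total RNA Ald (0.27) rose and X-linked Hex-A (−0.48) and Gapdh2 (−0.36) fell with the msl1 label, against 2 higher and 4 lower with the msl2 label (1 and 4 with autosomal scaling).

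Adjusted over the list alone, glycolysis gave 1 gene lower in TT-seq RNA with the msl1 label and 3 higher and 4 lower in total RNA with the msl2 label. Autophagy and lysosome gave 1 higher and 3 lower in total RNA with the msl1 label and 3 and 3 with the msl2 label. Ecdysone response gave 3 higher and 2 lower both in TT-seq RNA with the msl2 label and in total RNA with the msl1 label. Germline markers gave 2 higher and 1 lower, hemocyte markers 0 by limma and neural markers 1 lower in total RNA with the msl1 label, and neural markers 1 lower in TT-seq RNA with that label. In the remaining cases the number of calls adjusted over the list alone equalled that over all genes or stands beside it. Median, mean and test differed in sign, each with a median within 0.1 of 0 and no camera call, for the MSL complex with roX RNAs, RNA polymerase II genes, MSL interactors, RNAi machinery, Xrp1 response, ecdysone response, neural and hemocyte markers, glycolysis, autophagy, heat shock, ribosomal proteins and mitochondrial ribosomal proteins in at least 1 comparison.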
